A study of Homo sapiens with 14 samples.

How the data were processed

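Polyadenylated RNA of HCT116 cells was sequenced in 14 libraries, in 6 groups over 3 batches that the labels name. Per the labels' protocols, a Cas9-expressing clone was transfected with guide RNA plasmids to derive knockout clones, and knockdown used shRNA from a pLKO.1 vector. Per the submitters' processing notes, cutadapt 1.18, STAR 2.7.8a, featureCounts 2.0.1 and DESeq2 were used with genome build hg38; the notes give neither the role of each tool, the annotation release, the strand setting nor how gene identifiers were merged into symbols. The deposited table holds TPM values, 1 column per library, over 59409 gene symbols, and each column sums to 1000000. Of its columns, 0 could not be matched to a sample. Raw reads were not used here.

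The TPM values of a gene differ from library to library by steps of 1 read, so the reads assigned to each symbol were recovered by a search for the scale that makes them whole. With a tolerance of 0.1 read, 97.0% of tested symbols were whole in the first search and 0.03% with shifted factors, and finally 98.99% of tested symbols (17472) were whole. The totals ran from 9315121 to 22592986 per library and serve as depth; they also served alternative tests. Between replicates, Pearson's r of log2 values ran from 0.9686 to 0.9862.

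Symbols with at least 1 TPM in at least 2 libraries (17650) were tested. The values log2(TPM + 1) were fitted with limma 3.58.1 in R 4.3.3 as 6 group means over all 14 libraries, with 8 residual degrees of freedom, and tested two-sided with a moderated statistic whose variance prior follows the mean. Groups were compared within batches: DDX6 knockout (2) with control (4), EDC4 knockout (2) with control (2) and HMGA2 shRNA (2) with control shRNA (2). Further contrasts were the difference between both knockout effects and batch 1 against batch 2 controls. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A fold change of a gene with few reads depends on the pseudocount of 1. Relations between comparisons were computed across genes and as overlaps of calls beside the number expected if calls were independent. All comparisons share the spread fitted per gene, so calls are not fully independent and the expected numbers are a rough guide.

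The text names DDX6, EDC4 and HMGA2, the 8 genes with the largest rise and the 8 with the largest fall among called genes with at least 5 TPM on average in the higher group and libraries that do not overlap, up to 4 members with the smallest p from each list described, and 7 epithelial or mesenchymal genes. For the difference between knockouts it names 5 genes on each side. Clone, antisense, pseudogene and mitochondrial names were passed over, and some genes that the rule takes are not reported here. Genes named for their change in all 3 comparisons were chosen after their values were seen. The 25 gene lists were fixed from general knowledge and tested with camera, with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera asks whether a list's genes moved more than the other genes tested. Estimated correlation and fry were the alternatives. Fry tests whether a list's genes move one way on balance without comparing them with other genes, so a shift of most genes counts in it. The setting with an estimated correlation changed more than the correlation, as adjusted p also rose for lists estimated below 0.01. Colon differentiation genes in the EDC4 knockout, at -0.024, went from adjusted p = 0.000477 to 0.0357. A call lost with it therefore cannot be credited to correlated genes alone. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

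Gene positions come from the GENCODE v29 annotation of hg38, which held 17433 of the tested symbols (98.8%). Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

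The test was tried on simulated reads drawn from the real means and depths with 100 genes changed 2-fold and 100 changed 1.5-fold, each with a mean of at least 50 reads. In the DDX6 design 80% and 37% of these were recovered among 17034 genes, with 13 false calls among 134. In the EDC4 design 75% and 13% were recovered among 17038 genes (4 false calls of 95), in the HMGA2 design 64% and 19% among 17055 (1 of 84), and for the difference between knockouts 34% and 2% among 17022 (8 of 44). A list of 30 genes shifted by 0.4 was called in each of the 4 designs, and 0 of 20 random lists were. Simulated genes varied independently, while the estimated correlation within real lists reached 0.697 for glycolysis genes. The simulation thus cannot show how often lists of correlated genes are called falsely.

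The alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 TPM, median-of-ratios and quantile scaling, a fit of only the groups compared, a constant variance prior, replicate number as a block, a threshold of 2-fold, and leaving out each library in turn. With a group reduced to 1 library, that library is assumed to vary like the other groups. Chosen after seeing the data were scaling over nuclear genes, limma voom on recovered reads, reads thinned to the shallowest library, a fit without batch 3, batch 3 without symbols at 0 or 1 reads, and removal of each library's trend over GC content. Comparisons of 2 libraries with 2 or 4 give too few regroupings of the samples for a permutation test to reach the threshold.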

Results

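Messenger RNA was sequenced from 14 libraries of HCT116, a human colon cancer cell line, and its derivatives made with Cas9. Batch 1 held 4 control libraries and 2 libraries of cells with a knockout of DDX6, an RNA helicase of P-bodies, the cytoplasmic granules that hold translationally repressed mRNA. Batch 2 held 2 control libraries and 2 libraries of cells with a knockout of EDC4, a scaffold of the decapping complex. Batch 3 held DDX6 knockout cells with a control short hairpin RNA (shRNA, 2 libraries) or with an shRNA against HMGA2 (2 libraries), which encodes a chromatin protein and is a textbook target of the let-7 microRNA. The series title concerns P-bodies and epithelial-mesenchymal transition. The deposited values are TPM, which scale reads by gene length and library, for 59409 gene symbols, of which 36036 were above 0 in any library and 17650 reached 1 TPM in at least 2 libraries and were tested.

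The number of assigned reads per library, recovered from the steps between TPM values, ran from 9315121 to 22592986. The 4 batch 1 controls held 22130004, 18415296, 13143194 and 16950160 reads and the DDX6 knockout libraries 9315121 and 10818356. The batch 2 controls held 19242037 and 22592986 and the EDC4 knockout libraries 20920104 and 18551254. In batch 3 the control shRNA libraries held 19363223 and 17398044 and the HMGA2 shRNA libraries 17258240 and 20167059. Mitochondrially encoded transcripts took 21.6% ± 1.5 of the TPM in the batch 2 controls (SD, n = 2) and 37.2% ± 3.1 in the batch 1 controls (SD, n = 4). The knockout cells came from clones, and the labels do not say whether replicates of a group were separate clones or cultures. Each p-value rests on the spread between replicate libraries, pooled over all 6 groups. It may not measure the spread between clones, so an effect of a knockout cannot be told apart from a difference between clones. Fold changes below are limma estimates on log2(TPM + 1), and levels are mean TPM ± SD.

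The targeted genes were low where the labels place them. DDX6 (ENSG00000110367, chromosome 11, 118747766 to 118791149, hg38) stood at 88.9 ± 6.86 TPM in the batch 1 controls (n = 4) and 12.4 ± 2.27 in the DDX6 knockout (n = 2), a log2 change of -2.76 (SE 0.15, adjusted p = 7.35e-07). In batch 3, which was made from the knockout cells, it lay at 7.16 and 9.65 TPM with the control shRNA and at 7.49 and 6.22 with the HMGA2 shRNA. EDC4 (ENSG00000038358, chromosome 16, 67873023 to 67884503) stood at 72.0 and 83.1 TPM in the batch 2 controls and at 25 and 12.3 in the EDC4 knockout, a log2 change of -2.07 (SE 0.24, adjusted p = 0.000313). The 4 batch 1 controls held only 28.5, 28.1, 21.7 and 26.1 TPM of EDC4, close to the level of the EDC4 knockout libraries, and the other libraries of batches 1 and 3 lay between 18.8 and 31.2. HMGA2 (ENSG00000149948, chromosome 12, 65824131 to 65966295) was lower with its shRNA, at 37.9 ± 0.944 TPM against 54.1 ± 0.784 (n = 2 each, log2 change -0.51, adjusted p = 0.0274). That call was lost without control shRNA replicate 1 (adjusted p = 0.106), without control shRNA replicate 2 (0.106), without HMGA2 shRNA replicate 1 (0.111) and without HMGA2 shRNA replicate 2 (0.118), and with median-of-ratios scaling (0.0882).

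**Figure D1:**
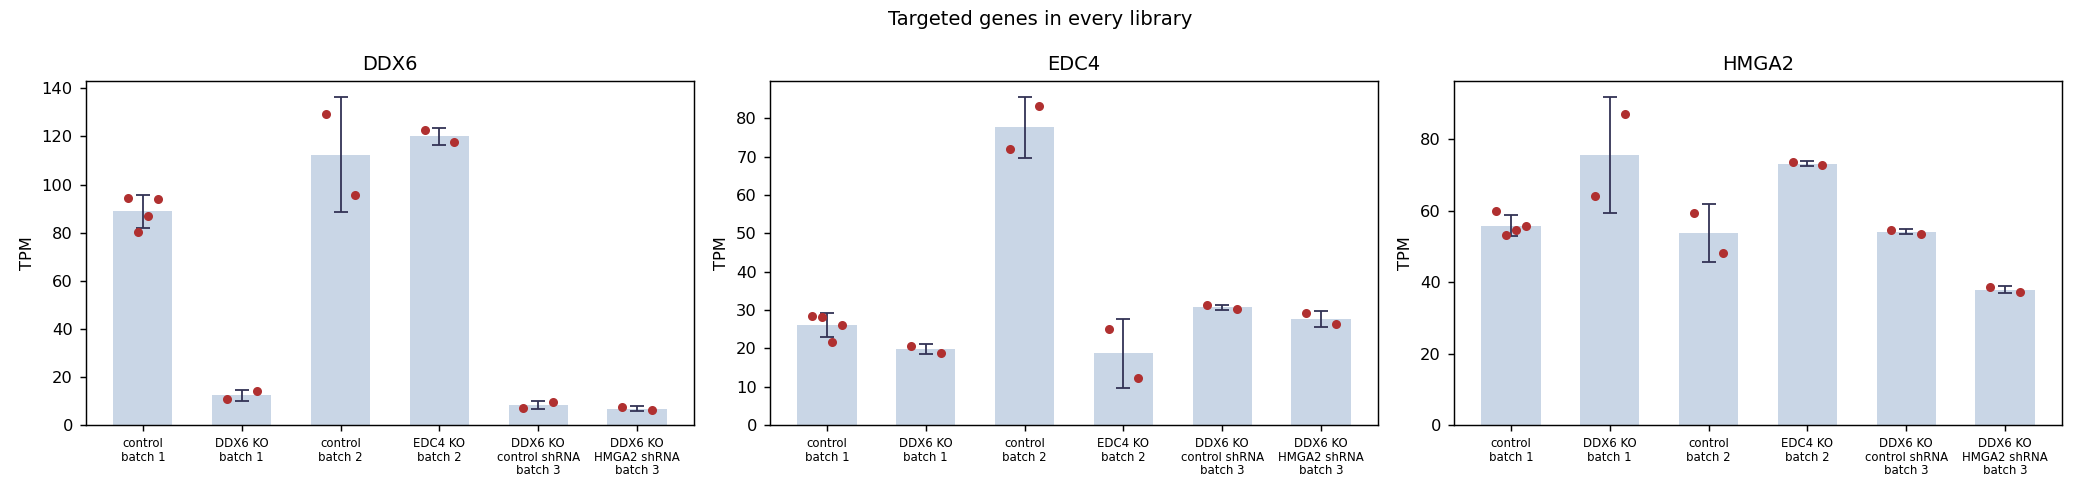
TPM of DDX6, EDC4 and HMGA2 in each of the 14 libraries, by group; points are libraries, bars group means and error bars SD. DDX6 lies at or below 14 TPM in all 6 libraries of DDX6 knockout cells, and EDC4 in the batch 1 controls, at 21.7 to 28.5 TPM, lies near its level in the EDC4 knockout.

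The comparison of DDX6 knockout with control cells asks what loss of this P-body helicase does to the transcriptome. Higher in the knockout were 25 of 36 interferon-stimulated genes, 13 of 20 antigen presentation genes and 13 of 23 mesenchymal markers, and lower were 20 of 30 glycolysis genes, 20 of 35 G1/S genes and 112 of 376 zinc finger genes. With an estimated correlation none of these lists kept its call, with adjusted p = 0.129, adjusted p = 0.225, adjusted p = 0.259, adjusted p = 0.427, adjusted p = 0.495 and adjusted p = 0.427 in this order. With fry all of them kept it, with adjusted p = 2.03e-05, 0.000111, 0.000111, 0.00574, 0.0185 and 0.0109 in the same order. APOBEC3G, a restriction factor against retroviruses, rose from 0.537 ± 0.458 TPM (n = 4) to 66.4 ± 72.2 (n = 2), and the extracellular matrix protein SPARC from 0.47 ± 0.0936 to 13.9 ± 2.5. The nuclear receptor NR2F1 fell from 203 ± 10.0 to 26.0 ± 12.7 TPM, and the Wnt ligand WNT16 from 56.9 ± 3.67 to 10.2 ± 3.23. In all, 3106 genes were higher and 2389 lower, and of these 427 and 305 changed at least 2-fold.

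Beside APOBEC3G (log2 change 4.88, SE 0.61, adjusted p = 0.000198) and SPARC (3.33, SE 0.71, adjusted p = 0.0044), the largest rises included those of HPGD (4.06), which degrades prostaglandins, the cytokine receptor subunit IL20RB (4.04), the ion channel HCN2 (3.18), the protease inhibitor SLPI (3.10) and perforin PRF1 (2.95). The knockout libraries differed in APOBEC3G, at 15.4 and 118 TPM, and its call held without either library. Beside NR2F1 (-3.00, SE 0.25, adjusted p = 1.65e-05) and WNT16 (-2.40, SE 0.16, adjusted p = 4.23e-06), the largest falls were those of secretogranin SCG2 (-2.14), DDN (-2.10), the transcription factor RUNX1 (-2.06) and the homeobox gene MKX (-1.93). MIRLET7A2, a let-7 locus that the same rule named, held 1 to 4 reads in the controls and is listed at 0 in the knockout.

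Of 36 interferon-stimulated genes tested, 25 rose, 1 fell and 10 were not called (29 and 1 when adjusted over the list alone), among them SAMD9 (1.86), IFI27 (1.57), DTX3L (1.30) and HERC6 (1.17). The list was called with camera (adjusted p = 1.5e-10), and with an estimated correlation its adjusted p = 0.129. Of 20 antigen presentation genes, 13 rose and none fell (14 and 0 adjusted over the list alone), including ERAP2 (1.06), TAPBP (0.79) and CALR (0.63), with adjusted p = 6.77e-06, and adjusted p = 0.225 with an estimated correlation. Unfolded protein response genes rose in 11 of 17 cases with 0 falling (11 and 0 adjusted over the list alone), such as HSP90B1 (0.50), PDIA6 (0.49) and HSPA5 (0.48). That list had adjusted p = 0.000241, and adjusted p = 0.427 with an estimated correlation.

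Mesenchymal markers were higher in 13 of 23 cases and lower in 2 (14 and 2 adjusted over the list alone), and 8 were not called. The adhesion molecule L1CAM (1.34), FSTL1 (1.17) and the receptor kinase AXL (1.04, from 16.9 ± 1.53 to 35.6 ± 0.844 TPM) were among those that rose. The list had adjusted p = 0.000718, and adjusted p = 0.259 with an estimated correlation. Epithelial markers went both ways, with 10 higher, 4 lower and 25 not called (10 and 4 adjusted over the list alone): KRT19 (0.82, and 0.48 without DDX6 knockout replicate 2) and the tight junction protein TJP1 (0.69) rose and MUC1 (-0.80) fell. Their test gave adjusted p = 0.303, and without DDX6 knockout replicate 1 adjusted p = 0.000284. E-cadherin CDH1 stood at 60.0 ± 4.15 TPM in the controls and 50 ± 21.5 in the knockout (log2 change -0.32, adjusted p = 0.211), and was called lower without DDX6 knockout replicate 2 (-0.77, adjusted p = 0.00209). Vimentin VIM stood at 3.68 ± 0.437 and 4.49 ± 4.24 TPM (adjusted p = 0.984), with the knockout libraries at 7.48 and 1.49, on opposite sides of the controls, and was called lower without DDX6 knockout replicate 1 (-0.91, adjusted p = 0.0492). EPCAM (0.20, adjusted p = 0.101) and SNAI2 (0.50, adjusted p = 0.11) were not called, but were called higher without DDX6 knockout replicate 1 (EPCAM, 0.31, adjusted p = 0.0484) and replicate 2 (SNAI2, 0.81, adjusted p = 0.0347). CDH2 was too low to be tested. The repressor ZEB1 was higher (0.77, adjusted p = 0.0357), with 1.36 without DDX6 knockout replicate 2, a call lost without DDX6 knockout replicate 1 (0.18, adjusted p = 0.505) and without each of control replicates 1 to 4 (0.066, 0.0575, 0.0566 and 0.0624). Fibronectin FN1 was lower (-0.52, adjusted p = 0.0491), with -0.93 without DDX6 knockout replicate 1, a call lost without DDX6 knockout replicate 2 (-0.11, adjusted p = 0.624) and without each of control replicates 1 to 4 (0.0939, 0.0849, 0.0506 and 0.0883).

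Glycolysis and hypoxia genes were lower in 20 of 30 cases and higher in 0 (0 higher and 24 lower adjusted over the list alone), with a median log2 change of -0.79. Examples are PDK1 (-1.60), HK2 (-1.47), GPI (-1.25, from 534 ± 39.9 to 224 ± 22.9 TPM) and PGAM1 (-0.92). The list had adjusted p = 1.5e-10, and adjusted p = 0.427 with an estimated correlation. The batch 1 controls held a mean of at least 6.94 over these genes on the log2 scale, above every library of batches 2 and 3. G1/S and DNA replication genes fell in 20 of 35 cases and rose in 1 (22 and 1 adjusted over the list alone), among them CDT1 (-0.84), MCM2 (-0.82) and UNG (-0.57). Their adjusted p = 5.35e-08, and adjusted p = 0.495 with an estimated correlation.

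Zinc finger genes with ZNF names, many of them transcriptional repressors, fell in 112 of 376 cases and rose in 17 (116 and 17 adjusted over the list alone), such as ZNF551 (-1.03), ZNF16 (-0.94) and ZNF580 (-0.90). The list had adjusted p = 5.35e-08, and adjusted p = 0.427 with an estimated correlation. Fold changes fell with the GC content of the gene across all genes (Spearman's rho -0.238, genes not being independent replicates). Ribosomal protein genes fell in 20 of 80 cases and rose in 3 (19 and 3 adjusted over the list alone), with RPSA at -0.59, adjusted p = 0.00194, and adjusted p = 0.847 with an estimated correlation. With fry that list was not called (adjusted p = 0.249). All histone values here are for polyadenylated RNA, and histone transcripts that are not polyadenylated may be missed. Histone genes of the replication-dependent clusters rose in 11 of 30 cases and fell in 0 (11 and 0 adjusted over the list alone), for example H2BC5 (1.92), H1-2 (1.80), H2AC6 (1.67) and H2BC12 (1.41). Their adjusted p = 0.0288, and adjusted p = 0.427 with an estimated correlation. The histone call was also lost without DDX6 knockout replicate 1 (adjusted p = 0.145) and without control replicate 1 (0.0849).

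Among 42 P-body and decay factors, 7 rose, 8 fell and 27 were not called (8 and 8 adjusted over the list alone), with ZFP36 up by 0.98 and PAN2 (-1.05) and ZFP36L2 (-0.98) down, and the list was not called (median 0.07, adjusted p = 0.895). DDX6 is itself 1 of the 8 that fell, and without it the mean change of the list was 0.03 (adjusted p = 0.837), against -0.04 with it. Of 27 mRNAs with known let-7 sites, 10 rose and 4 fell (11 and 4 adjusted over the list alone, adjusted p = 0.288). HMGA2 itself rose from 55.8 ± 2.84 to 75.5 ± 16.2 TPM (0.41, adjusted p = 0.0174), with 0.63 without DDX6 knockout replicate 1, a call lost without DDX6 knockout replicate 2 (0.20, adjusted p = 0.227). In batch 3, DDX6 knockout cells with the control shRNA held 54.7 and 53.6 TPM of HMGA2, within the 53.2 to 59.8 of the batch 1 controls. Batch 3 thus does not show the rise, though it has no wild-type control. Of 15 Wnt target genes, 4 rose and 5 fell (4 and 5 adjusted over the list alone, adjusted p = 0.515), with DKK1 (1.09) higher and NOTUM (-1.83), MYC (-1.38, from 208 ± 18.6 to 80.1 ± 20 TPM) and the adhesion receptor CD44 (-0.93) lower. TGF-beta pathway genes rose in 11 of 34 cases and fell in 5 (13 and 6 adjusted over the list alone, adjusted p = 0.158), with FSTL3 (1.35) and SMURF2 (0.68) higher and CCN1 (-0.97) lower. G2/M genes were not called (adjusted p = 0.651, and adjusted p = 0.922 with an estimated correlation). The test pointed in opposite directions without either knockout library, lower without replicate 1 and higher without replicate 2. The G2/M list mean on the log2 scale was 6.57 in knockout replicate 1 and 6.15 in replicate 2, on opposite sides of the controls (6.32 to 6.47).

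Of the 107 called genes that the naming rule took for the DDX6 knockout, 93 kept their call without each of the 6 libraries in turn. With median-of-ratios scaling 2922 genes were higher and 3121 lower.

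The comparison of EDC4 knockout with control cells asks the same of a second P-body component. Of interferon-stimulated genes 19 of 36 rose, of antigen presentation genes 9 of 20, of colon differentiation genes 6 of 11 and of epithelial markers 14 of 39, and 11 of 22 ATF4 and stress response genes fell. With an estimated correlation adjusted p = 0.0357 for each of the first 3 lists, while epithelial markers (adjusted p = 0.307) and ATF4 genes (adjusted p = 0.0753) lost their calls. With fry all of these lists kept theirs, with adjusted p = 0.0162 for epithelial markers and 0.00067 for ATF4 genes. The bone transcription factor RUNX2 rose from 1.63 ± 0.43 TPM to 20.8 ± 2.63 (n = 2 each) and the desmosomal cadherin DSC3 from 1.46 ± 0.739 to 16.9 ± 0.526. The neurotrophin BDNF fell from 23.1 ± 1.2 to 6.42 ± 0.389 TPM and WNT16 from 102 ± 7.42 to 32.0 ± 7.3. In all, 1098 genes were higher and 365 lower, 348 and 67 of them at least 2-fold. With median-of-ratios scaling 980 were higher and 614 lower, with quantile normalization 926 and 620, and with the GC trend removed 1346 and 1028.

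The largest rises also included EHF (3.56, SE 0.67, adjusted p = 0.00766), an epithelial transcription factor, APOBEC3G (3.29), the tetraspanin TSPAN1 (3.10), SLPI (2.87) and the protease KLK5 (2.85), beside RUNX2 (3.06, SE 0.30, adjusted p = 0.000117) and DSC3 (2.90, SE 0.34, adjusted p = 0.000404). Beside BDNF (-1.70, SE 0.10, adjusted p = 3.88e-06) and WNT16 (-1.67, SE 0.18, adjusted p = 0.000271), the largest falls were those of keratin KRT7 (-2.72), ARHGAP29 (-2.27), TMEM200A (-1.58), the collagen COL12A1 (-1.51) and SCG2 (-1.46). Of the 90 called genes that the naming rule took for this comparison, 45 kept their call without each of the 4 libraries in turn. The number lost was 25 without control replicate 1, 41 without control replicate 2, 34 without EDC4 knockout replicate 1 and 37 without EDC4 knockout replicate 2. APOBEC3G, TSPAN1, SLPI, KRT7 and COL12A1 lost theirs in all 4 cases (adjusted p from 0.054 for APOBEC3G without control replicate 1 to 0.277 for KRT7 without EDC4 knockout replicate 2). TMEM200A lost its call without control replicates 1 and 2 (adjusted p = 0.11 and 0.141) and EDC4 knockout replicate 1 (-0.97, adjusted p = 0.214), and EHF without control replicate 2 (0.07) and EDC4 knockout replicate 1 (0.0505).

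Of 36 interferon-stimulated genes, 19 rose, 0 fell and 17 were not called (24 and 0 adjusted over the list alone), among them SAMD9 (1.59), IFIH1 (1.51), DTX3L (0.98) and PARP9 (0.88). The list had adjusted p = 8.05e-13 and kept its call with an estimated correlation (adjusted p = 0.0357). Antigen presentation genes rose in 9 of 20 cases with 0 falling (15 and 0 adjusted over the list alone), including the class II genes HLA-DRB1 (2.25) and HLA-DRA (1.92), PSMB10 (1.26) and ERAP1 (1.11). Colon differentiation genes rose in 6 of 11 cases with 0 falling (6 and 1 adjusted over the list alone), including the mucin MUC13 (2.54) and CEACAM1 (1.19). Their adjusted p values were 8.14e-10 and 0.000477, and both lists had adjusted p = 0.0357 with an estimated correlation.

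Epithelial markers rose in 14 of 39 cases and fell in 1, with 24 not called (23 and 2 adjusted over the list alone). The protease ST14 (0.94, from 136 ± 12.9 to 260 ± 16 TPM) and CDS1 (0.60) rose, and the list had adjusted p = 1.64e-08, and adjusted p = 0.307 with an estimated correlation. CDH1 rose from 40.2 ± 3.47 to 81.2 ± 3.81 TPM (1.00, adjusted p = 0.0149), a call lost without control replicate 2 (adjusted p = 0.115), EDC4 knockout replicate 1 (0.0578) and EDC4 knockout replicate 2 (0.104). Mesenchymal markers rose in 5 of 23 cases and fell in 2 (12 and 2 adjusted over the list alone), with S100A4 (1.69, from 99.1 ± 7.69 to 322 ± 5.97 TPM) and L1CAM (1.19) among those higher. That list had adjusted p = 0.00921, adjusted p = 0.279 with an estimated correlation and adjusted p = 0.0607 without control replicate 1. FN1 was called higher (0.83, adjusted p = 0.0329) but not without control replicates 1 or 2 (adjusted p = 0.0966 and 0.158) or EDC4 knockout replicates 1 or 2 (0.0506 and 0.24). VIM (-0.78, adjusted p = 0.343), ZEB1 (-0.57, adjusted p = 0.28) and EPCAM (0.35, adjusted p = 0.0513) were not called.

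TGF-beta pathway genes rose in 9 of 34 cases and fell in 2 (15 and 2 adjusted over the list alone), including BMP4 (1.63, from 291 ± 1.76 to 909 ± 138 TPM), the inhibitor SMAD7 (1.39), LTBP3 (0.96) and SMURF2 (0.82). Their adjusted p = 7.49e-05, and adjusted p = 0.256 with an estimated correlation. BMP4 stood at 858 to 920 TPM in the batch 1 controls and at 648 to 860 in the DDX6 knockout and batch 3 libraries. Only the batch 2 controls were low, and the EDC4 knockout lay near the batch 1 controls. Wnt targets rose in 7 of 15 cases and fell in 1 (9 and 2 adjusted over the list alone), with RNF43, a membrane inhibitor of the pathway, up by 1.30, and adjusted p = 0.000376, or adjusted p = 0.143 with an estimated correlation. ATF4 and stress response genes fell in 11 of 22 cases and rose in 0 (0 higher and 16 lower adjusted over the list alone), among them asparagine synthetase ASNS (-1.16), PSAT1 (-0.73) and the amino acid transporter SLC7A5 (-0.72, from 609 ± 66.3 to 369 ± 9.29 TPM). Their adjusted p = 1.23e-11, and adjusted p = 0.0753 with an estimated correlation. The means of this list on the log2 scale were 6.05 and 6.17 in the batch 2 controls and 5.66 and 5.74 in the EDC4 knockout libraries, and 5.08 to 5.58 in all libraries of batches 1 and 3, so the batch 2 controls lie above all other libraries. G1/S genes fell in 2 of 35 cases (5 adjusted over the list alone), with UNG at -0.58, adjusted p = 1.58e-06, and adjusted p = 0.481 with an estimated correlation. P-body and decay factors fell in 3 of 42 cases, 1 of them EDC4 itself, and rose in 0, with adjusted p = 0.0139, adjusted p = 0.553 with an estimated correlation and adjusted p = 0.145 without control replicate 1. Without EDC4 the list had adjusted p = 0.037, and adjusted p = 0.587 with an estimated correlation.

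Several lists were called with few called members. Of those below, fry kept NF-kB genes (adjusted p = 0.00685) and unfolded protein response genes (0.0269). It did not keep p53 targets (0.0737), glycolysis genes (0.365), ribosomal protein genes (0.3), zinc finger genes (0.615) or G2/M genes (0.615). NF-kB genes rose in 4 of 17 cases and fell in 1, with adjusted p = 0.00324, and adjusted p = 0.281 with an estimated correlation. Unfolded protein response genes rose in 2 of 17 cases (adjusted p = 0.00124, and adjusted p = 0.349 with an estimated correlation), and p53 targets in 4 of 25, with CDKN1A at 0.62 (adjusted p = 0.0478, and adjusted p = 0.562 with an estimated correlation). The p53 call was lost without control replicate 2 (adjusted p = 0.232) and without EDC4 knockout replicate 1 (0.399). Glycolysis genes rose in 2 of 30 cases, SLC2A1 (1.37) among them, and fell in 1. Their adjusted p = 0.0478, and adjusted p = 0.685 with an estimated correlation, and the test pointed the other way without control replicate 1 (adjusted p = 0.999) and EDC4 knockout replicate 2 (0.533). Ribosomal protein genes had a median of -0.15 with 0 of 80 called in either direction (adjusted p = 6.16e-07, and adjusted p = 0.553 with an estimated correlation). Zinc finger genes rose in 10 and fell in 14 of 376 cases (adjusted p = 0.0116, and adjusted p = 0.629 with an estimated correlation), and the call was lost without control replicate 1 (adjusted p = 0.178). G2/M genes had 0 of 38 called (adjusted p = 0.017, and adjusted p = 0.672 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.0707).

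The test of the EDC4 knockout rests on the spread pooled over all 6 groups: fitted on its own 4 libraries, limma called 0 genes, with 3462 at an unadjusted p under 0.05, while limma voom on recovered reads called 2488 in the fit of all groups. The count of 1463 called genes became 947 without control replicate 1, 469 without control replicate 2, 820 without EDC4 knockout replicate 1 and 526 without EDC4 knockout replicate 2.

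Whether the 2 knockouts had different effects was tested as a difference of differences. Each knockout has controls of its own batch only, so a different effect cannot be told apart from a difference of the control cells. Genes higher in one knockout tended to be higher in the other: 628 genes rose in both (193.2 expected if the calls were independent) and 186 fell in both (49.4 expected), while 11 rose in the DDX6 knockout and fell in the EDC4 knockout (64.2 expected) and 50 did the reverse (148.6 expected). Across genes, which are not independent replicates, fold changes correlated with r = 0.328 (Spearman's rho 0.336). The effects differed for 1037 genes, 408 with a higher change in the DDX6 knockout and 629 with a lower one. This split depends on the scaling, with 674 and 816 by median-of-ratios, 824 and 924 by quantile normalization and 973 and 902 with the GC trend removed. KRT7 (difference of log2 changes 4.81), HCN2 (2.93), IL20RB (2.24), BDNF (2.23) and GLIS3 (2.23) were relatively higher in the DDX6 knockout. CEMIP (-3.36), ANGPTL4 (-3.12), HSD17B1 (-2.83) and TMEM125 (-2.76) were relatively lower. KRT7 stood at 1.75 to 3.03 TPM in the batch 1 controls and at 55.3 and 98.5 in the batch 2 controls. Its knockout levels overlapped, at 8.15 and 17.6 (DDX6) and 15.8 and 6.67 (EDC4). ANGPTL4 controls likewise differed, at 53.8 to 70.2 against 6.82 and 11.5. HCN2 controls were close, at 1.60 to 1.93 against 3.04 and 3.33, and its knockouts differed, at 22.6 and 26.3 against 3.63 and 4.31. KRT7 lost its call without batch 2 control replicate 2 (adjusted p = 0.0579) and EDC4 knockout replicate 2 (0.0863), and IL20RB without batch 2 control replicate 1 (0.0535) and EDC4 knockout replicate 2 (0.0655). ANGPTL4 lost its call without batch 1 control replicates 2 and 4 (0.0589 and 0.0558), DDX6 knockout replicate 1 (0.0814), batch 2 control replicates 1 and 2 (0.119 and 0.0515) and EDC4 knockout replicate 2 (0.111).

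Glycolysis and hypoxia genes differed in 17 of 30 cases, all lower in the DDX6 knockout relative to the EDC4 knockout (24 adjusted over the list alone; adjusted p = 1.17e-15, and adjusted p = 0.599 with an estimated correlation). Epithelial markers were relatively lower in 4 of 39 cases and higher in 1 (13 and 2 adjusted over the list alone; adjusted p = 0.00166, and adjusted p = 0.786 with an estimated correlation), a call lost without DDX6 knockout replicate 1 (adjusted p = 0.187). CDH1 was among those lower (-1.32, adjusted p = 0.0223, and -0.88 without DDX6 knockout replicate 1), as was FN1 outside the list (-1.35, adjusted p = 0.0203). CDH1 lost its call without batch 2 control replicates 1 or 2 (adjusted p = 0.0602 and 0.0652) or EDC4 knockout replicates 1 or 2 (0.0548 and 0.0885), and FN1 without batch 2 control replicates 1 or 2 (0.063 and 0.053) or EDC4 knockout replicate 2 (0.0911). The count of 1037 became 575 without batch 1 control replicate 2, 539 without batch 1 control replicate 4, 347 and 653 without batch 2 control replicates 1 and 2, and 564 and 234 without EDC4 knockout replicates 1 and 2.

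**Figure D2:**
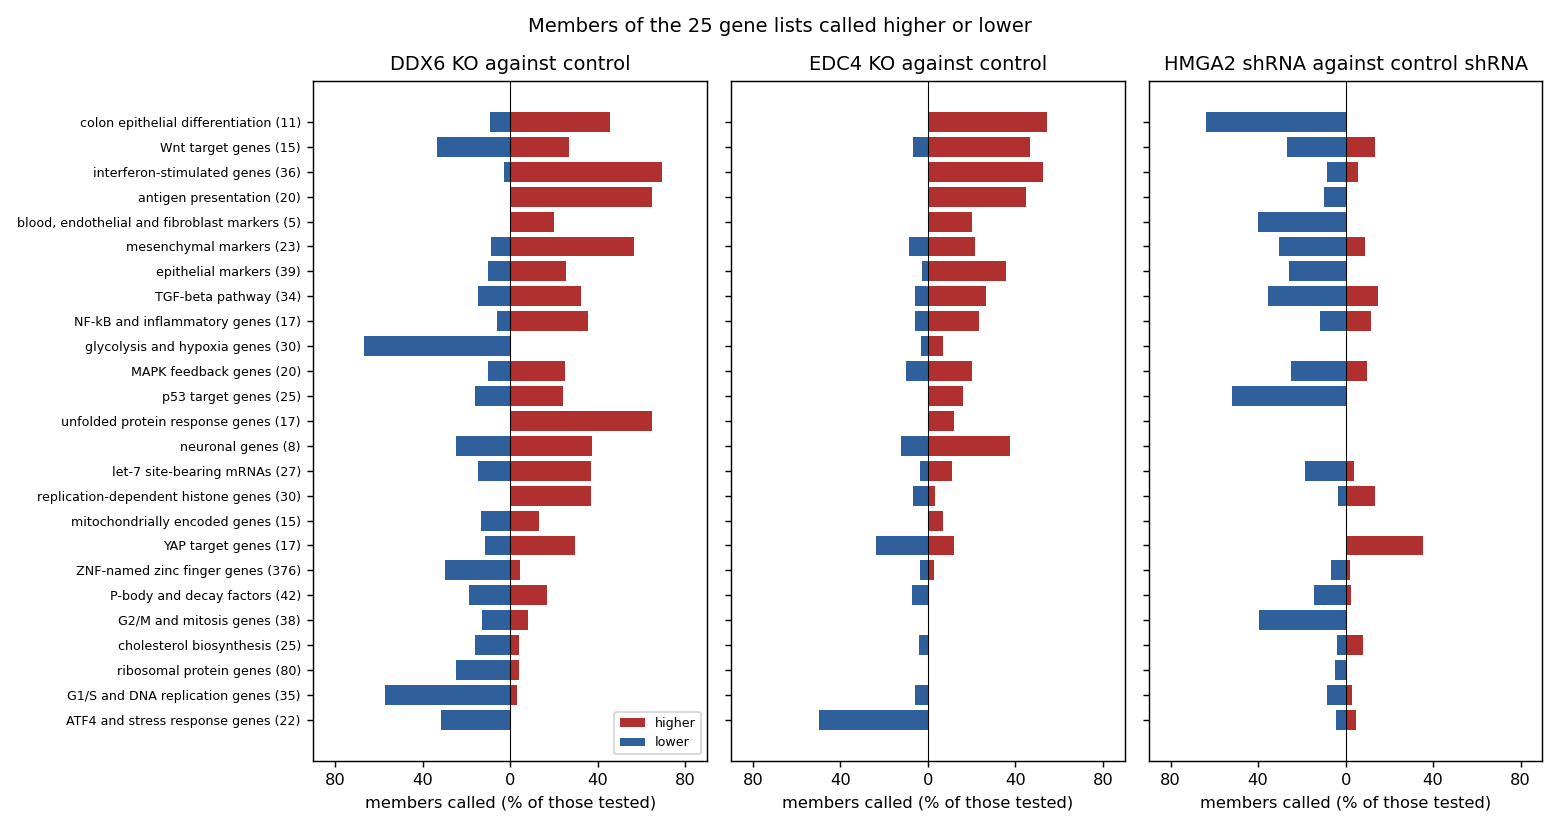
Percent of the tested members of each of the 25 gene lists called higher (red, to the right) or lower (blue, to the left) in the 3 comparisons, with the number tested in brackets. Of 36 interferon-stimulated genes, 25 were higher in the DDX6 knockout and 19 in the EDC4 knockout, and of 25 p53 target genes 13 were lower with the HMGA2 shRNA.

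The comparison of the HMGA2 shRNA with the control shRNA asks which genes of DDX6 knockout cells change when HMGA2 is lowered. Lower were 13 of 25 genes of the p53 pathway, 15 of 38 G2/M genes, 7 of 11 colon differentiation genes and 10 of 39 epithelial markers, and 6 of 17 YAP targets were higher. With an estimated correlation only colon differentiation genes kept their call (adjusted p = 0.0324, but adjusted p = 0.134 without symbols at 0 or 1 reads in a library of batch 3), against adjusted p = 0.195 for p53, adjusted p = 0.848 for G2/M genes, adjusted p = 0.883 for epithelial markers and adjusted p = 0.173 for YAP targets. With fry all were kept, with adjusted p = 0.00028 for p53, 0.0467 for G2/M genes and for epithelial markers, 1.28e-06 for colon differentiation genes and 0.00393 for YAP targets. The cell cycle inhibitor CDKN1A fell from 214 ± 1.15 to 66.8 ± 4.69 TPM (n = 2 each), and the receptor kinase AXL rose from 27.5 ± 0.38 to 68.2 ± 0.565. Histone genes H1-2 and H2BC12 rose from 69.9 ± 6.96 to 296 ± 77.1 TPM and from 94.3 ± 4.97 to 398 ± 124. These are levels in polyadenylated RNA, which may miss other histone transcripts. In all, 341 genes were higher and 1994 lower, 116 and 436 of them at least 2-fold. This split depends on the scaling: the median change over all genes was -0.13 as deposited and 0.01 with median-of-ratios scaling, which gave 1133 higher and 1164 lower, while quantile normalization gave 964 and 954 and scaling over nuclear genes 666 and 1484.

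Among the largest rises were ARHGAP29 (2.40, SE 0.38, adjusted p = 0.00225), H1-2 (2.05, SE 0.29, adjusted p = 0.0012), H2BC12 (2.03, SE 0.21, adjusted p = 0.000111), NR2F1 (1.93, SE 0.29, adjusted p = 0.00145), RUNX1 (1.93) and ZNF804A (2.79). SPRR3 and SPRR2D, which encode cornified envelope proteins, rose from 0 to 3 reads with the control shRNA to 26 to 128 reads. SPARC fell from 152 ± 8.25 TPM to 14.6 TPM, or 396 reads, in HMGA2 shRNA replicate 1 and to 1 read in replicate 2. TSPAN1 fell from 60.0 ± 0.951 to 7.73 ± 10.6 TPM (-3.76, adjusted p = 0.00919) and EHF from 53.4 ± 1.4 to 7.75 ± 9.78 (-3.34, adjusted p = 0.00803), calls lost without control shRNA replicate 2 (adjusted p = 0.0565 and 0.0537), and without HMGA2 shRNA replicate 2 the changes were -1.91 and -1.80. TRGV8, TAS2R19, KISS1 and IL34, at 21.7, 17.8, 13.7 and 10.4 TPM with the control shRNA, held 0 or 1 reads in the HMGA2 shRNA libraries, and PABPN1L, at 8.51 TPM, is listed at 0. Of the 436 genes at least 2-fold lower, 189 held 0 or 1 reads in a library of batch 3, and of the 116 at least 2-fold higher, 67 did. Without such genes, 287 were higher and 1910 lower, 53 and 253 of them at least 2-fold.

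Of 25 p53 target genes, 13 fell, 0 rose and 12 were not called (0 higher and 18 lower adjusted over the list alone), including TP53INP1 (-1.77), CDKN1A (-1.67, SE 0.09, adjusted p = 2.26e-06), the DNA repair gene DDB2 (-1.12) and GADD45A (-0.64). The list had adjusted p = 4.86e-08, and adjusted p = 0.195 with an estimated correlation. G2/M and mitosis genes fell in 15 of 38 cases and rose in 0 (0 higher and 19 lower adjusted over the list alone), with adjusted p = 3.06e-05, and adjusted p = 0.848 with an estimated correlation. Its members CENPA (-0.62) and CDK1 (-0.61) lost their calls without control shRNA replicate 2 (adjusted p = 0.0643 and 0.0598) and without HMGA2 shRNA replicate 1 (0.0887 and 0.0575). Colon differentiation genes fell in 7 of 11 cases with 0 rising (0 higher and 9 lower adjusted over the list alone), including CDX2 (-0.87, from 22.6 to 11.9 TPM) and CA2 (-0.68). Their adjusted p = 3.06e-05, and they were the 1 list of this comparison that kept its call with an estimated correlation (adjusted p = 0.0324). That call depends on genes with few reads, such as PHGR1, with 31 and 24 reads with the control shRNA and 0 and 1 with the HMGA2 shRNA. Without symbols at 0 or 1 reads in a library of batch 3, 6 of the 8 genes left fell, with adjusted p = 0.000604, and adjusted p = 0.134 with an estimated correlation.

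YAP target genes rose in 6 of 17 cases with 0 falling (10 and 0 adjusted over the list alone): AXL (1.28), F3 (1.11) and CCN1 (1.11) were higher. The list had adjusted p = 4.64e-10, and adjusted p = 0.173 with an estimated correlation. Epithelial markers fell in 10 of 39 cases and rose in 0 (0 higher and 15 lower adjusted over the list alone), including ELF3 (-1.44), TJP3 (-1.40) and the splicing regulator ESRP1 (-0.95, from 103 ± 0.457 to 52.8 ± 4.04 TPM). Their adjusted p = 0.00333, and adjusted p = 0.883 with an estimated correlation. EPCAM fell (-0.51, adjusted p = 0.00684), a call lost without control shRNA replicate 2 (adjusted p = 0.0626), while CDH1 (-0.69, adjusted p = 0.0542), VIM (0.79, adjusted p = 0.28), ZEB1 and SNAI2 were not called. Mesenchymal markers fell in 7 of 23 cases and rose in 2 (10 and 2 adjusted over the list alone, adjusted p = 0.465), with S100A4 (-1.61) and TAGLN (-1.12) lower and AXL higher. HMGA2 itself is 1 of the 7, and without it 6 of 22 fell (adjusted p = 0.624). With fry the list that holds HMGA2 had adjusted p = 0.0184. The list of blood, endothelial and fibroblast markers was called lower (median -0.86, adjusted p = 0.0472), and had adjusted p = 0.272 with an estimated correlation. That call was lost without control shRNA replicate 2 (adjusted p = 0.083) and HMGA2 shRNA replicate 1 (0.0805), and without symbols at 0 or 1 reads in a library of batch 3 too few members were left for a test.

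Some lists were called higher relative to the other genes, whose median change was -0.13. With fry, cholesterol, histone and interferon-stimulated genes had adjusted p = 0.587, 0.287 and 0.564, so none of these lists was called to move by itself. Of 25 cholesterol biosynthesis genes, 2 rose and 1 fell, and the list was called higher in this sense with adjusted p = 0.00592, and adjusted p = 0.848 with an estimated correlation. Histone genes rose in 4 of 30 cases and fell in 1, with adjusted p = 0.00519, and adjusted p = 0.31 with an estimated correlation, and adjusted p = 0.17 with median-of-ratios scaling. Interferon-stimulated genes rose in 2 of 36 cases, IFITM3 (0.69) and IFITM2 (0.60), and fell in 3, with adjusted p = 0.00968 for the list, adjusted p = 0.582 with an estimated correlation and adjusted p = 0.129 without HMGA2 shRNA replicate 2.

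The count of 2335 called genes became 1256 without control shRNA replicate 1, 882 without control shRNA replicate 2, 838 without HMGA2 shRNA replicate 1 and 1072 without HMGA2 shRNA replicate 2, and 270 when the 4 libraries were fitted alone. Of the 87 called genes that the naming rule took, 49 kept their call without each library in turn.

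Genes that rose in the DDX6 knockout tended to be lower with the HMGA2 shRNA. Of the 3106 genes higher in the knockout, 765 fell with the shRNA (350.9 expected if the calls were independent) and 44 rose (60.0 expected). Of the 2389 lower in the knockout, 113 rose (46.2 expected) and 172 fell (269.9 expected). With median-of-ratios scaling 454 genes went from higher to lower (192.7 expected) and 418 from lower to higher (200.3 expected). SPARC, APOBEC3G and SLPI fell with the shRNA after rising in the knockout, and NR2F1, RUNX1 and ARHGAP29 rose after falling. For SPARC the fall started from a control shRNA level far above that of the batch 1 knockout. In HMGA2 shRNA replicate 1 (396 reads) its TPM lay near that knockout level, and replicate 2 held 1 read. Without HMGA2 shRNA replicate 2 the falls were smaller for SPARC (-3.30 against -5.26) and SLPI (-1.65 against -3.17). Across genes the fold changes correlated weakly, with r = -0.158 (Spearman's rho -0.169), and with r = -0.105 without DDX6 knockout replicate 2. The 2 comparisons share no library, but they share the spread fitted per gene.

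**Figure D3:**
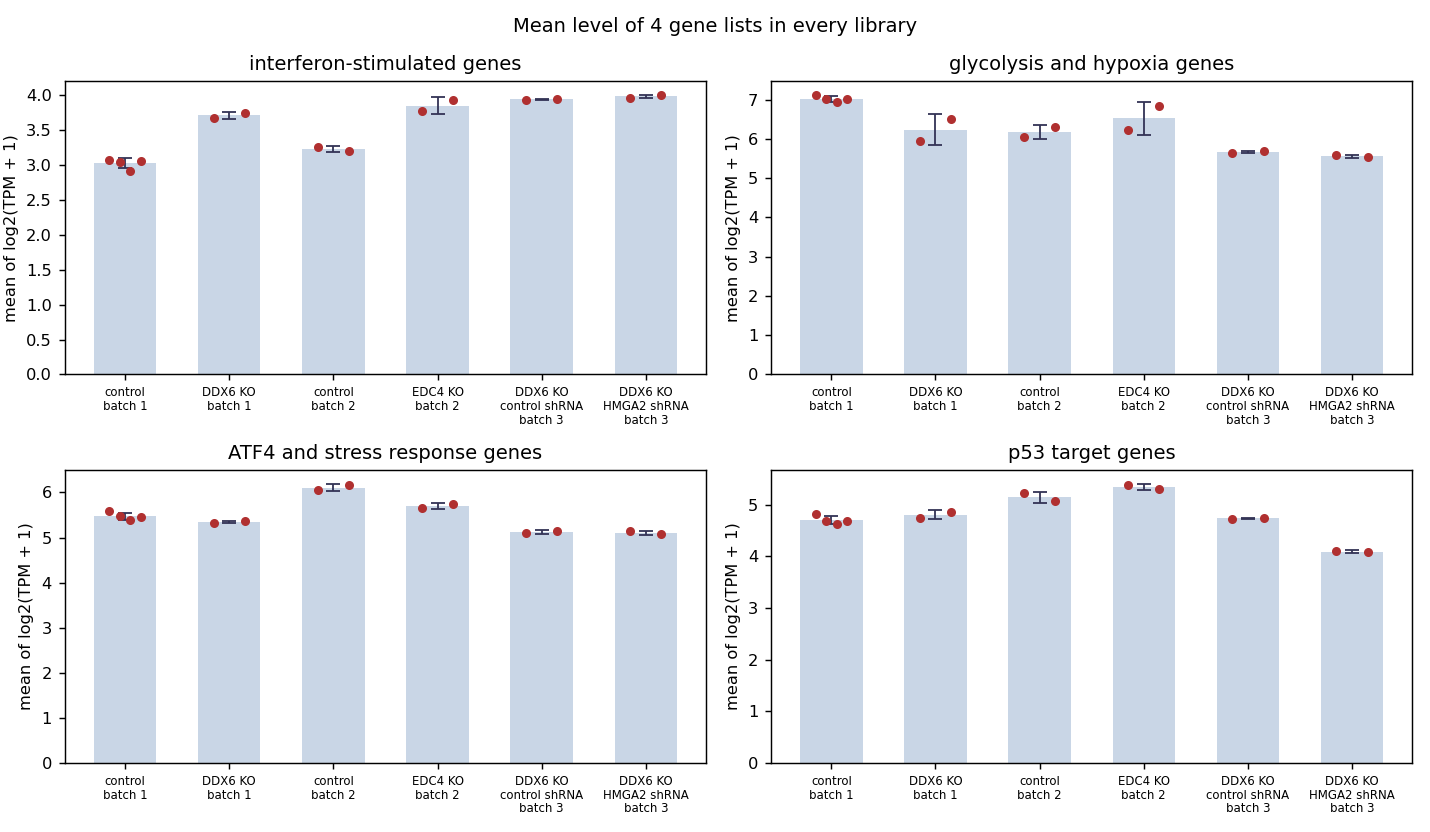
Mean log2(TPM + 1) over the genes of 4 lists in each of the 14 libraries, by group; points are libraries, bars group means and error bars SD. Glycolysis and hypoxia genes lie at 6.94 to 7.12 in the batch 1 controls and at 5.53 to 6.83 in all other libraries.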

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

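The tests of causes in this part were all chosen after the results were seen. The difference between the effects of the knockouts of DDX6 and EDC4 was tested gene by gene and differed for 1037 genes. As each knockout has controls of its own batch only, these differences may also reflect the control cells. The genes named for this difference were DDX6 (-2.87), EDC4 (1.70), KRT7 (4.81), HCN2 (2.93), IL20RB (2.24), BDNF (2.23), GLIS3 (2.23), CEMIP (-3.36), ANGPTL4 (-3.12), HSD17B1 (-2.83), TMEM125 (-2.76), CDH1 (-1.32) and FN1 (-1.35), as differences of log2 changes. Of these 13 genes, 8 kept their call without each library in turn; ANGPTL4, CDH1, FN1, IL20RB and KRT7 lost it in at least 1 case, among them all 5 without EDC4 knockout replicate 2 (adjusted p = 0.111, 0.0885, 0.0911, 0.0655 and 0.0863).

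Lists whose change differed between the knockouts were glycolysis and hypoxia genes (adjusted p = 1.17e-15), Wnt targets (0.00114), epithelial markers (0.00166), ZNF-named zinc finger genes (0.00166), replication-dependent histone genes (0.00166) and ATF4 and stress response genes (0.00184). With an estimated correlation these adjusted p values were 0.599, 0.461, 0.786, 0.786, 0.461 and 0.786. With fry they were 0.0333, 0.00439, 0.246, 0.19, 0.0333 and 0.0648. Wnt targets were relatively lower in the DDX6 knockout in 7 of 15 cases and higher in 1, ATF4 genes higher in 3 of 22, zinc finger genes lower in 23 of 376 and histone genes higher in 6 of 30. The ATF4 call was lost without batch 2 control replicate 2 (adjusted p = 0.0954), and the epithelial call without DDX6 knockout replicate 1 (adjusted p = 0.187).

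The glycolysis and hypoxia genes were lower in the DDX6 knockout than in its controls. A single knockout library is excluded as the cause, since the list stayed lower without either of them (higher adjusted p = 1.27e-06) and both list means lie below all controls, though with an estimated correlation over all libraries the list had adjusted p = 0.427. High levels in the batch 1 controls are a candidate explanation: their lowest list mean, 6.94 on the log2 scale, lies above the highest of batches 2 and 3, 6.83, while of the knockout libraries, at 5.95 and 6.51, 1 lies below and 1 within the range of 6.06 to 6.83 of the batch 2 libraries. An effect of DDX6 loss stays open, as the highest knockout mean of 6.51 lies below all batch 1 controls; it cannot be told apart from a difference of those controls, because batch 3, which also holds DDX6 knockout cells, has no wild-type control.

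In batch 3, 63 genes stood at 5 TPM or more in both control shRNA libraries and below 1 TPM in both HMGA2 shRNA libraries, against 10 the other way. At its control shRNA level as deposited, the median gene would hold 70 reads in the HMGA2 shRNA libraries (lowest 3.2), and 62 of the 63 held 0 or 1. Taken as they stand, these values argue against too few reads for the median gene. The control values may themselves have been altered, so the test cannot exclude it. In both knockout libraries of batch 1, 6 of the 63 reached 1 TPM, so most did not stand high in the DDX6 knockout there. That comparison is across batches, so it does not exclude a fall from such levels in batch 3. Values of genes with few reads may have been altered before deposit: of symbols whose highest read number in batch 3 was 20 to 49, 17.99% shared all 4 read numbers with another symbol, against 0.58% and 0.59% in batches 1 and 2. An effect of the HMGA2 shRNA on some of these genes was not excluded.

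Fold changes in the DDX6 knockout fell with GC content (rho -0.238 across genes). A GC trend between libraries whatever their group is a candidate explanation, since differences between replicates correlated with GC content at up to 0.485. A shift with loss of DDX6 cannot be told apart from it: the knockout libraries lay beyond the nearest control by 0.023, while the 4 controls spanned 0.358. The lower level of the zinc finger genes was not accounted for by this trend, as their median log2 change was -0.292 with the trend removed (adjusted p = 2.38e-11), though before its removal the list had adjusted p = 0.427 with an estimated correlation.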

How the results depend on the processing

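Alternatives chosen after seeing the data were scaling over nuclear genes, voom on recovered reads, thinned reads, the fit without batch 3, batch 3 without symbols at 0 or 1 reads, removal of the GC trend, lists without the targeted gene, and symbols at 0 or 1 reads left out with an estimated correlation. The change of DDX6 in its knockout kept direction and call in every alternative and without each library (-2.93 to -2.44), and that of EDC4 kept direction (-2.56 to -1.59) and its call except when only its groups were fitted (-2.07, adjusted p = 0.13). HMGA2 with its shRNA lost its call with no filter (-0.51), median-of-ratios (-0.33), quantile (-0.35), only the groups compared (-0.51), nuclear genes (-0.42) and without each library (-0.53 to -0.48). Counts of called genes with a 2-fold threshold were 732 for DDX6, 415 for EDC4, 552 for HMGA2, 411 for the difference between knockouts and 729 between control batches, fewer by construction. Fitting only the groups compared gave 0 for EDC4 (3462 at an unadjusted p under 0.05; voom 2488), 270 for HMGA2 and 587 for the difference, with fewer residual degrees of freedom. Voom gave 1800 for the difference, quantile normalization 1748, the fit without batch 3 587 and GC removal 1875, and GC removal gave 2374 for EDC4. Without each library in turn the counts ran from 469 to 947 for EDC4, 838 to 1256 for HMGA2, 4176 to 5208 for DDX6 and 234 to 1420 for the difference. The correlation of DDX6 and EDC4 changes was 0.208 and 0.412 with pseudocounts 0.1 and 5, 0.294 with no filter, 0.465 at a mean of 5 TPM, 0.289 on thinned reads and 0.26 to 0.333 without each library; that of DDX6 and HMGA2 was -0.10 and -0.205, -0.221 at a mean of 5 TPM, -0.136 over nuclear genes, -0.135 thinned, -0.24 without symbols at 0 or 1 reads and -0.174 to -0.105 without each library. Lists called fell with an estimated correlation from 9 to 0 (DDX6), 17 to 3 (EDC4), 10 to 1 (HMGA2; 0 without symbols at 0 or 1 reads) and 6 to 0 (difference); fry called 11 for EDC4 and 3 for the difference, and the difference had 6 to 10 without each library. Epithelial markers had adjusted p = 0.307 (EDC4) and 0.883 (HMGA2; 0.796 without symbols at 0 or 1 reads) with an estimated correlation and 0.000284 to 0.444 (DDX6) without each library. Mesenchymal markers had 0.259 (DDX6) and 0.279 (EDC4) with an estimated correlation, 0.0718 with no filter (EDC4), 0.00241 to 0.0607 without each library (EDC4) and 0.0184 with fry (HMGA2). The direction of a list test reversed for G2/M genes for DDX6 (0.00446 without knockout replicate 2; range without each library 4.86e-05 to 0.824) and for the difference (0.0281 without DDX6 knockout replicate 1; 4.95e-06 to 0.368), for glycolysis genes for EDC4 (0.999 without control replicate 1 and 0.533 without knockout replicate 2; lowest 3.01e-06) and for ribosomal protein genes for HMGA2 (0.0451 without HMGA2 shRNA replicate 2; 0.00171 to 0.527). Without the targeted gene P-body factors had adjusted p = 0.837 (DDX6) and 0.037 (EDC4), and mesenchymal markers 0.624 (HMGA2). Except where stated, the cause was not tested.

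The replicate numbers show no pairing in the values: correlations between equal numbers of the groups compared were 0.018, 0.041 and 0.001. With replicate number as a block, 2959 genes were called for DDX6, 425 for EDC4, 821 for HMGA2 and 10 for the difference, and HMGA2 itself had -0.51 (adjusted p = 0.11).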

Other observations

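The overlap over all 3 comparisons was chosen for testing after the results were seen. Of the genes tested, 317 were higher in both knockouts and lower with the HMGA2 shRNA, where 21.8 were expected if calls were independent, and 34 were lower in both and higher with the shRNA (1.0 expected). In contrast, 9 were higher in all 3 (3.7 expected) and 4 lower in all 3 (5.6 expected). The comparisons share the spread fitted per gene, so these expected numbers are a rough guide. With median-of-ratios scaling the groups held 213 (10.7 expected) and 127 (7.0 expected), and with replicate number as a block 73 and 12. When only the groups compared were fitted both held 0, as limma then called 0 genes for EDC4, with 3462 at an unadjusted p under 0.05 and 2488 by voom in the fit of all groups. Of the 317 genes, 5 held 0 or 1 reads in a library of batch 3.

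Chosen after their values were seen, examples from the 317 genes are the secreted antimicrobial protein SLPI (3.10 in the DDX6 knockout, 2.87 in the EDC4 knockout and -3.17 with the HMGA2 shRNA), the cytidine deaminases APOBEC3G (4.88, 3.29 and -2.87) and APOBEC3F (2.50, 2.32 and -1.59), keratin KRT13 (1.72, 2.51 and -2.75), perforin PRF1 (2.95, 2.38 and -1.93), HPGD (4.06, 2.57 and -2.30) and RUNX2 (1.74, 3.06 and -1.77). The cell cycle inhibitor CDKN1A belonged to them too (0.42, 0.62 and -1.67). In the opposite group were NR2F1 (-3.00, -1.39 and 1.93), ARHGAP29 (-1.65, -2.27 and 2.40), MKX (-1.93, -1.33 and 1.06) and WNT16 (-2.40, -1.67 and 0.72). Without each library in turn, APOBEC3F, PRF1, RUNX2, CDKN1A and ARHGAP29 kept their calls in all 3 comparisons. At least 1 call was lost for SLPI (highest adjusted p = 0.12), APOBEC3G (0.147), KRT13 (0.0705), HPGD (0.126), NR2F1 (0.0926), MKX (0.122) and WNT16 (0.126). Without HMGA2 shRNA replicate 2 the changes with the shRNA were smaller for SLPI (-1.65), KRT13 (-1.79), HPGD (-1.20) and RUNX2 (-1.13), as was that of HPGD in the EDC4 knockout without EDC4 knockout replicate 1 (1.86) and that of ARHGAP29 in the DDX6 knockout without DDX6 knockout replicate 2 (-0.92).

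The changes in the EDC4 knockout and with the HMGA2 shRNA were also opposed. Of 1098 genes higher in the EDC4 knockout, 470 were lower with the shRNA (124.0 expected) and 21 higher (21.2 expected), and of 365 lower in the knockout, 54 were higher (7.1 expected) and 14 lower (41.2 expected). With median-of-ratios scaling 322 went from higher to lower (64.6 expected) and 191 from lower to higher (39.4 expected), and with the GC trend removed 446 (110.2 expected) and 291 (71.5 expected). Across genes r was -0.197 (Spearman's rho -0.238). These comparisons share neither libraries nor a batch, but they share the spread fitted per gene.

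The control cells of batches 1 and 2 differed at 6915 genes, more than the 5495 called for the DDX6 knockout. Of these, 959 were higher and 5956 lower in batch 1, with a median change of -0.24 over all genes. With median-of-ratios scaling 2410 were higher and 2462 lower. Scaled over nuclear genes 2405 were higher and 2315 lower, with a median change of 0.02. The excess of lower genes was thus absent once mitochondrially encoded transcripts were left out of the scaling. These took 37.2% of the TPM in the batch 1 controls and 21.6% in the batch 2 controls. EDC4 was among those lower in batch 1 (-1.54). Glycolysis and hypoxia genes were higher in batch 1 in 20 of 30 cases as deposited and 24 with median-of-ratios scaling, while G1/S genes were lower in 33 and 23 of 35 cases and ATF4 genes in 18 and 13 of 22. Mitochondrially encoded genes were higher in 13 of 15 cases in both. Quantile normalization left 4 of them higher (median -0.07). As it gives every library the same set of values, it cannot show a shift of genes that hold the highest ones. With an estimated correlation none of these lists was called (adjusted p = 0.403 for each as deposited). With fry as deposited all were called, with adjusted p = 0.0108 for glycolysis, 0.000413 for G1/S, 3.6e-05 for ATF4 and 0.000413 for mitochondrially encoded genes. In the HMGA2 comparison 0 of 15 mitochondrially encoded genes were called, with a median of 0.15 and adjusted p = 0.00519 for the list, and adjusted p = 0.848 with an estimated correlation; that call was lost without control shRNA replicate 2 (adjusted p = 0.0667) and HMGA2 shRNA replicate 2 (0.134). With fry the mitochondrial list of the HMGA2 comparison had adjusted p = 0.475. Of 53 values tested for a library apart from the other batch 1 controls, 0 were found.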
